A study of Mus musculus with 2 samples.

How the data were processed

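Total RNA of the P5424 mouse T-cell line was measured on 2 one-colour Agilent mouse gene expression arrays with 60-base probes. Per the labels, both samples are untreated P5424 cells that lack Rag2 and P53 (gene symbol Trp53), grown in RPMI1640 with fetal bovine serum and 2-mercaptoethanol. Per the labels' protocols, RNA was extracted with Trizol, amplified and labelled with Cy3. The 2 arrays form 1 group and are called replicate 1 and replicate 2 as in the labels. The labels do not say whether the replicates are separate cultures, so the spread between them may be technical. Both arrays lie on 1 slide, so slide cannot separate them.

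The scanner values are intensity values that, per the file headers, the authors obtained from Agilent Feature Extraction 10.5.1.1 on 1-colour images. Per the file headers, that software subtracted a fitted spatial background, removed a multiplicative trend over the array and replaced signals near background by surrogate values. The deposited values were not scaled between arrays. A column with the trend surface itself was first listed for a position check but not used, because a grid of spot differences was used instead. The second kind of value is a table of log2 values that the authors deposited for the same spots, with scale and centring unstated. Set against the scanner values of the same array, its slope on the log2 scale over spots well above background was 0.997 on replicate 1 and 1.01 on replicate 2, with Pearson r = 1.000 across spots on each, where spots are not independent replicates. Its column medians were both 5.18, and after sorting the columns differed by at most 0.0125, as quantile normalization over all spots gives. The size of any offset added by the authors and the background step behind the floor at 5.13 stay unknown. Probe positions in the files are on the mouse build mm9. Whether a position lies in an exon or a UTR was not analysed here.

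Each array holds 62976 spots, of which 59305 are not controls. They form 55681 probes, 55249 of them with 1 spot and 399 with 10 spots. Spots that the software marked as non-uniform or as population outliers were left out, which removed 182 spots on replicate 1 and 186 on replicate 2. No spot was saturated. For each array, log2 of the processed signal was averaged over the spots of a probe and the array's 75th percentile over all non-control probes was subtracted, so that a value of 0 is the 75th percentile of that array. That percentile was 324 intensity units on replicate 1 and 299 on replicate 2. Because 40.1% of the probes were detected on both arrays, the percentile over detected probes was run as an alternative.

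A probe was called detected when the software marked it well above background on both arrays (at least 50% of the spots for a probe with several). A gene was called detected when any of its probes was, and not well above background when all its probes failed on both arrays. A gene's value is that of its detected probe with the highest mean. A probe that is not well above background has only an upper bound, so no level is given for it. Signal was used to choose a gene's probe and to tell the Rag2 probes apart by name, but no amount of transcript was inferred from one probe relative to another. Probes were named through their accession (26762 probes), symbol (3819) or a unique synonym (639) in a RefSeq gene table of assembly GRCm38.p6, which was used for names alone. This gave 22221 genes, and 24461 probes without a reference gene kept the name in the files.

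Before the data were examined, 27 gene lists, the main tests and the alternatives were fixed. Tests and alternatives added later are named as such where their results are given. Of 497 list entries, 491 matched a gene on the array and 6 did not, and 1 duplicate within a list was dropped. The genes named are the first 4 detected and the first 3 not detected members of each list in its fixed order, both genes labelled as knocked out, all members of the X-inactivation and Y-linked list, and every member of a list's smaller class where that class has 5 or fewer members. For the difference between the arrays they are the 5 genes with the largest difference in each direction. A few genes that fall under this rule are left out of the text and of the plot of thymocyte stages, but are kept in every count. Any other gene is said to be chosen after its values were seen. The number of detected members of a list was set beside the central 95% of 10000 random lists of the same size, drawn from the named genes of the array and matched on the number of probes per gene. Detection of T-lineage genes was compared with 9 other lists by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 9 comparisons. Genes are not independent replicates, so these p-values compare the lists on these arrays. There was no second condition and therefore no test between groups. The number of arrays limits the precision of every value.

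Alternatives covered the scaling (array median, 75th percentile over detected probes, quantile normalization), normexp background correction with an offset of 50, the authors' log2 table, outlier and saturated spots kept, other detection criteria, and each array left out. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The steps were tested on simulated data for the difference between the replicate arrays, built from the 22321 detected probes. All 200 probes shifted 4-fold were found over 2-fold apart in the right direction, and 7 unshifted probes were. The simulated noise was the same at every signal level and the shift lay well over the cut. This checks the computation only and gives no error rate for the real arrays.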

Results

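P5424 is a mouse T-cell line of immature thymocyte origin, and its labels give it as untreated and lacking Rag2, a subunit of the recombinase that assembles antigen receptor genes, and the tumour suppressor P53. Its transcriptome was profiled on 2 one-colour arrays, replicate 1 and replicate 2. Values below are log2 signals relative to the 75th percentile of their array, given as mean ± SD of the 2 arrays (n = 2). Replicate 1 had 23649 of 55681 probes well above background (42.5%) and replicate 2 had 22923 (41.2%). The 308 negative control spots had a median signal of 6.55 intensity units on replicate 1 and 7.50 on replicate 2, with 0 and 1 of them well above background. The file headers give an R² of the spike-in series of 0.994 on replicate 1 and 0.992 on replicate 2. The headers mark the mean net signal of the negative controls, 53.8 and 59.5 units, as out of range on both arrays.

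The genes labelled as knocked out were measured first. Both Rag2 probes and the Trp53 probe were well above background on both arrays. The brighter Rag2 probe (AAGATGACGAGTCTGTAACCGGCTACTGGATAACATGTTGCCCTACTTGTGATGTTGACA) lies at chromosome 2, 101470723 to 101470782 of mm9, and starts at base 1430 of transcript NM_009020. It had a value of 2.76 ± 0.06, with signals of 2132 and 2086 intensity units. The other Rag2 probe (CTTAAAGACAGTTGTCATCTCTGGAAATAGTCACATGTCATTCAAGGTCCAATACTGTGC), at 101472445 to 101472504 and base 3152 of the transcript, had a value of -1.81 ± 0.07 with signals of 90.2 and 88.5. The Trp53 probe (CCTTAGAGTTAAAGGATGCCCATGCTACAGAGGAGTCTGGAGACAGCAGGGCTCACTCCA) lies at chromosome 11, 69404204 to 69404263, base 1187 of NM_011640, and had a value of 1.47 ± 0.38 with signals of 746 and 996. The labels do not give the deleted part of either gene. A probe outside the deleted part checks nothing about a knockout, so these signals neither bear out nor contradict the genotype label.

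Across the array, 11496 of 22221 named genes were detected on both arrays (51.7%), 571 were found on 1 array and 10154 on neither. On replicate 2, 1 negative control spot reached 101 intensity units, and 1317 of the detected genes (11.5%) had a signal below it. Of the genes named below, these include Il2ra, Cd44, Krt14, Ins2, Cd79a, Vpreb1, Cd14, Klf1, Zbtb16 and Cd163l1. On replicate 1 the highest control spot was at 15.1 units, and 0 detected genes lay below it. Genes with 1 probe were detected in 45.1% of cases, those with 2 probes in 64.4% and those with 3 or more in 72.2%. Of 20125 protein-coding genes, 10888 were detected (54.1%), against 346 of 1559 genes annotated as long non-coding RNA (22.2%).

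Most genes of the T-lineage programme were detected. All 23 surface and signalling genes of the T lineage were detected, where random lists gave 8 to 17. Among them were the CD3 chains of the T-cell receptor complex, with Cd3e at 8.31 ± 0.17 (chromosome 9, 44806828 to 44806887 of mm9), Cd3g at 7.17 ± 0.03, Cd3d at 8.91 ± 0.06 and Cd247 at 1.83 ± 0.51. Of 22 T-lineage transcription factors, 20 were detected (random lists 8 to 17), including Tcf7 at 5.47 ± 0.04, Gata3 at 4.14 ± 0.09, Bcl11b, which enforces T-cell commitment, at 6.05 ± 0.01, and Notch1 at -0.15 ± 0.18. Tox, a factor of positively selected thymocytes, was found on 1 array, and Zbtb17 was not well above background.

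Genes of neighbouring thymocyte stages were detected side by side. The list for the CD25-positive double-negative stage that precedes beta-selection (DN3) had 11 of 15 members detected, with random lists at 4 to 11. Ptcra, which encodes the pre-T-cell receptor alpha chain, had a value of 5.52 ± 0.25 (chromosome 17, 46892827 to 46892886). Dtx1 and Notch3, of the Notch pathway, had 6.69 ± 0.52 and 4.79 ± 0.17. Il2ra, which encodes CD25, was detected at -2.31 ± 0.25, with signals of 57.9 and 68.3 intensity units, the latter below the highest negative control spot of replicate 2. The 4 DN3 genes not well above background were Hes1, Il7r (the interleukin 7 receptor alpha chain), Nrarp and Erg. The list of genes that rise after beta-selection or mark CD4 and CD8 double-positive cells had 13 of 17 detected, with random lists at 5 to 13. Both coreceptors were among them, with Cd4 at 5.71 ± 0.03, Cd8a at 5.79 ± 0.18 and Cd8b1 at 5.53 ± 0.18. Egr1, Egr2 and Egr3, the immediate early factors induced by receptor signalling, were not well above background, and the activation marker Cd69 was found on 1 array. Both lists stayed within the range of random lists, so their counts do not set them apart from other genes on the array. The count for the second list passed the range under 4 alternatives: detection on 1 array sufficing or replicate 1 left out (14 genes, upper limit 13), a positive and significant signal (16, upper limit 15) and every probe of a gene required (13, upper limit 12).

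**Figure D1:**
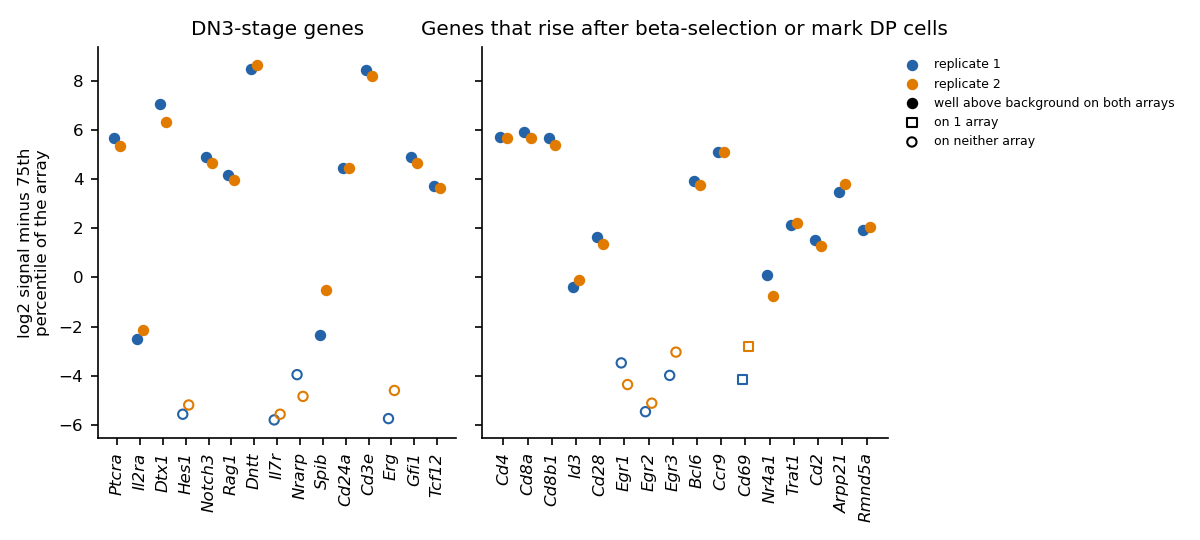
Log2 signal minus the array's 75th percentile (y axis) of 15 DN3-stage genes and 16 genes that rise after beta-selection or mark double-positive cells (x axis), 1 point per array. Filled points are well above background on both arrays (11 and 12 genes), squares on 1 array, and open circles on neither, where the point is only an upper bound; heights of different genes cannot be compared with each other.

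Genes of other lineages were detected less often than the T-lineage surface and signalling genes. Only 3 of 18 progenitor genes were detected (random lists 5 to 13): Kit at 0.97 ± 0.04, Flt3 at -1.44 ± 0.15 with 1 of its 3 probes, and Cd44 at -2.99 ± 0.27 with 1 of its 4 probes. Spi1, Lyl1 and Hhex, regulators of multipotent progenitors, were not well above background. Of 20 thymic stromal, fibroblast and endothelial genes, 5 were detected (random lists 6 to 14), namely Ccl25, Pdgfrb, Pecam1, Kdr and Krt14. Ccl25 was detected with 3 of its 4 probes and Kdr with 1 of its 2. The epithelial genes Foxn1, Krt5 and Krt8 were not detected. Of 20 genes of liver, nerve, muscle and pancreas, Snap25 (4.01 ± 0.07) and Ins2 (-2.88 ± 0.07) were detected (random lists 6 to 15), and Alb, Apoa1 and Ttr were not. Fisher's exact test gave adjusted p = 5.79e-08 for the T-lineage list against the progenitor list, 3.07e-07 against stroma and 2.81e-09 against other tissues. With the weaker criterion of a positive and significant signal, 10 progenitor, 12 stromal and 10 other-tissue genes were detected, and these 3 lists then lay inside the range of random lists.

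Lists of other blood lineages lay inside the range of random lists, most of them only at its lower limit, and below the T-lineage list. The myeloid (6 genes, random lists 6 to 15), natural killer (6, random lists 6 to 14) and erythroid (3, random lists 3 to 9) lists were at that limit. The B-cell list (8, random lists 5 to 13) was not. Of 18 B-cell genes, 8 were detected, among them Cd79a at -2.74 ± 0.11 with 1 of its 2 probes, the adaptor Blnk at 1.06 on replicate 1 and 0.94 on replicate 2, Vpreb1 at -1.81 ± 0.23 and Cd22 at -1.44 ± 0.18. Cd79b was found on 1 array, and the B-cell commitment factor Pax5 was not well above background. Of 20 myeloid genes, 6 were detected, including Csf1r at -1.61 ± 0.63, Itgam at 4.40 ± 0.17, Elane at -1.27 ± 0.32 and Cd14 at -2.76 ± 0.13. Csf1r and Itgam were each detected with 2 of their 3 probes. Mpo and Emr1 were found on 1 array, and lysozyme (Lyz2) was not well above background. Of 18 natural killer and innate lymphoid genes, 6 were detected, including Gzma, a cytotoxic granule protease, at 8.00 ± 0.01, Nkg7 at 1.36 ± 0.16, Prf1 at -1.15 ± 0.04 and Id2 at 2.64 ± 0.15. Nkg7 was detected with 1 of its 2 probes. The receptors Klrb1c, Ncr1 and Klrd1 were not well above background. With a positive and significant signal, 14 B-cell, 14 myeloid and 6 erythroid genes were detected, and the T-lineage share exceeded the B-cell share by 22.2 percentage points (exact test, adjusted p = 0.0340) where the main criterion gave 55.6. The natural killer list then fell below the range of random lists (8 genes, lower limit 9), as did the myeloid list with every probe required (3 genes, lower limit 5). Of 13 erythroid and megakaryocyte genes, Gata1 at -0.54 ± 0.05, Klf1 at -2.19 ± 0.05 and Epor at 3.98 ± 0.09 were detected, and the globins Hba-a1 and Hbb-b1 were not. Fisher's exact test against the T-lineage list gave adjusted p = 5.02e-05 for B-cell, 1.11e-06 for myeloid, 3.53e-06 for natural killer and 2.03e-06 for erythroid genes.

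Mature T-cell and gamma-delta genes were mixed. Of 20 mature or effector T-cell genes, 10 were detected, including Ifng at -1.28 ± 1.11, Ccr7 at -0.63 ± 0.52 and Tbx21 at 1.08 ± 0.04. Foxp3, Il17a and Il4 were not well above background. The gamma-delta list lost 4 entries, all for T-cell receptor gamma segments, because their names matched no gene on the array. Those segments are absent from the count and test that follow. Among probes found by description, the gamma constant probe was not well above background, and no gamma variable probe was detected on both arrays. Of 7 gamma-delta T-cell genes, 5 were detected, namely Cd163l1 at -1.44 ± 0.69, Sox13 at -1.33 ± 0.16, Zbtb16 at -2.79 ± 0.23, Blk at -1.86 ± 0.43 and Maf at -0.80 ± 0.38 with 1 of its 2 probes, and Il23r and Etv5 were not. Fisher's exact test gave adjusted p = 0.000108 for the T-lineage list against mature T-cell genes and 0.0483 against gamma-delta genes. The latter call was lost with a positive and significant signal as the criterion (adjusted p = 0.233).

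**Figure D2:**
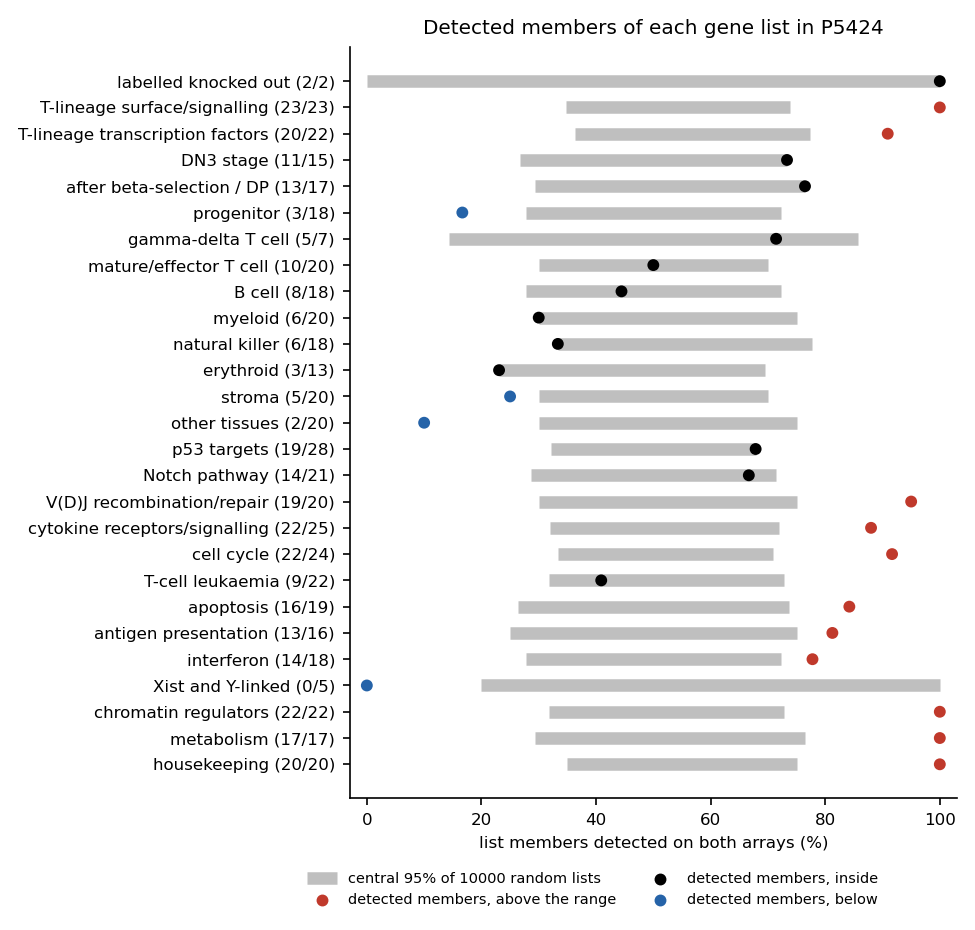
Share of each gene list's members that were detected on both arrays (x axis, percent), with the counts beside each name (y axis); grey bars are the central 95% of 10000 random lists of the same size and probe numbers. Of the 27 lists, 11 lay above that range, 4 below it and 12 inside it.

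Recombination and repair genes were nearly all detected, and p53 target genes were divided. Of 20 genes of V(D)J recombination and DNA break repair, 19 were detected (random lists 6 to 15). Rag1, the partner of Rag2, had a value of 4.06 ± 0.14 (chromosome 2, 101478813 to 101478872), terminal transferase (Dntt) 8.58 ± 0.11 (chromosome 19, 41133936 to 41133995), and the Ku subunits Xrcc6 and Xrcc5 had 7.74 ± 0.05 and 3.14 ± 0.04. Brca1 was found on 1 array. Of 28 genes that p53 is known to activate, 19 were detected, at the upper end of random lists (9 to 19), including Mdm2 at 4.64 ± 0.22, Bbc3 at 0.98 ± 0.52, Bax at 4.08 ± 0.06 and Fas at -0.51 ± 0.15. Cdkn1a, which encodes the cell cycle inhibitor p21, was not well above background with any of its 3 probes, nor were Pmaip1 and Tnfrsf10b. Of 19 BCL2 family and apoptosis genes, 16 were detected (random lists 5 to 14). Bcl2l1 had a value of 6.23 ± 0.01, Mcl1 6.14 ± 0.01, Bcl2 -0.89 ± 0.40 and Bcl2l11 -0.84 ± 0.48, while Pmaip1, Hrk and Fasl were not well above background. The p53 list passed its range when every probe of a gene was required (upper limit 18), and the apoptosis list fell inside its range with a positive and significant signal (upper limit 16).

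Notch, cytokine and leukaemia genes were detected in part. Of 21 Notch pathway genes, 14 were detected (random lists 6 to 15), including Dtx1, Notch3, Ptcra and Myc, the last at 4.71 ± 0.07, while Hes1, Nrarp and Hes5 were not well above background. Of 25 cytokine receptors and their signalling genes, 22 were detected (random lists 8 to 18). The common gamma chain Il2rg had a value of 4.01 ± 0.12, Il4ra -0.57 ± 0.28 with 1 of its 2 probes, and Il6ra 1.26 ± 0.29, and the 3 members not well above background were Il7r, Il2rb and Cish, a target of STAT5. Of 22 T-cell leukaemia and tumour suppressor genes, 9 were detected (random lists 7 to 16). Cdkn2a, which encodes p16 and p19ARF, had a value of 6.35 ± 0.39 (chromosome 4, 88920405 to 88920464), Cdkn2c 2.22 ± 0.25 and Fbxw7 2.03 ± 0.04. Cdkn2b and the leukaemia factor Tal1 were not well above background.

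Genes of proliferation, energy metabolism and chromatin were detected almost without exception. Of 24 cell cycle genes, 22 were detected (random lists 8 to 17), with Mki67 at 6.45 ± 0.00, Top2a at 4.90 ± 0.36, Ccnb1 at 5.12 ± 0.13 and Ccna2 at 5.91 ± 0.14, and Aurkb and Ccnd2 were not well above background. All 17 glycolysis and nutrient uptake genes were detected (random lists 5 to 13), including the glucose transporters Slc2a1 at 2.23 ± 0.07 and Slc2a3 at 3.18 ± 0.14 and the hexokinases Hk1 at 6.69 ± 0.01 and Hk2 at 0.71 ± 0.13. All 22 chromatin regulators were detected (random lists 7 to 16), including the Polycomb genes Ezh2 at 4.42 ± 0.18, Suz12 at 4.13 ± 0.10 and Eed at 4.74 ± 0.13 and the methyltransferase Dnmt1 at 5.14 ± 0.11. All 20 housekeeping genes were detected (random lists 7 to 15), with Actb at 9.61 ± 0.10, Gapdh at 9.49 ± 0.08 and Hprt at 6.11 ± 0.01, besides B2m.

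Antigen presentation and interferon-induced genes were detected more often than in random lists. Of 16 antigen presentation genes, 13 were detected (random lists 4 to 12), with the class I genes B2m at 6.93 ± 0.27, H2-K1 at 2.93 ± 0.29 and H2-D1 at 4.78 ± 0.42 and the transporter Tap1 at 1.67 ± 0.09. The class II genes H2-Aa and H2-Eb1 and their transactivator Ciita were not well above background. The class II genes H2-Ab1 and H2-DMa, named after their values were seen, were detected at -0.58 ± 0.22 and -0.09 ± 0.15. Of 18 interferon-induced genes, 14 were detected (random lists 5 to 13), including Ifit1 at 0.13 ± 0.17, Ifit2 at -0.11 ± 0.11, Isg15 at 6.47 ± 0.29 and Oas1a at -1.52 ± 0.13 with 1 of its 2 probes. Ifit3 and Irf7 were found on 1 array, and Oasl2 and Ifih1 on neither. This list fell inside the range of random lists when replicate 2 was left out (14 genes, range 6 to 14) or when every probe of a gene had to be detected (11 genes, range 4 to 12). None of the 5 X-inactivation and Y-linked genes (Xist, Ddx3y, Kdm5d, Uty, Eif2s3y) was well above background on either array, where random lists gave 1 to 5. Requiring every probe of a gene moved the range of random lists to 0 to 4, which includes that count. Xist and the Y-linked genes are active in opposite sexes, so random lists are no matched reference for this list.

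The 2 arrays gave nearly the same values. Across the 22321 detected probes, Pearson's r was 0.994 and Spearman's rho 0.992, where probes are not independent replicates, and the median absolute difference was 0.18. The 7 spike-in controls that were measured differed by a median of 0.07 before scaling and 0.19 after it. Among 207 detected probes printed on 10 spots, the median SD of the spots was 0.06 on replicate 1 and 0.07 on replicate 2, and 120 of these probes (58.0%) differed between the arrays by more than 3 standard errors of their spots. Of the 11496 detected genes, 90 (0.783%) were over 2-fold apart, 61 higher on replicate 2 and 29 higher on replicate 1. With 1 array per replicate, no test per gene was possible. Scaling by the array median moved the median difference of detected probes to -0.23 and turned this split to 34 and 96, and normexp background correction left 34 genes over 2-fold apart (26 and 8).

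The genes higher on replicate 1 by the widest margin were Ceacam16 (4.66-fold), Cirbp (3.91-fold), Dmbt1 (3.55-fold), 5830411N06Rik (3.33-fold) and Hdgfl3 (2.99-fold). Those higher on replicate 2 were Hbs1l (4.92-fold), Cox10 (4.68-fold), Hpn (4.35-fold), Trip11 (4.12-fold) and Phb (4.01-fold). Where other detected probes of these genes existed, most did not show the difference. The other probe of Cirbp, which encodes a cold-induced RNA-binding protein, differed by 0.30 in the opposite direction, and the 2 other Hbs1l probes by -0.33 and -0.30, also in the opposite direction, as did the other Trip11 probes by -0.49 and -0.20. The other probe of Phb, which encodes a mitochondrial chaperone, differed by 0.06. The other Hdgfl3 probe was lower on replicate 2 by a smaller margin (-0.34). The other 5830411N06Rik probe was lower on replicate 2 as well, with a log2 difference of -1.08.

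**Figure D3:**
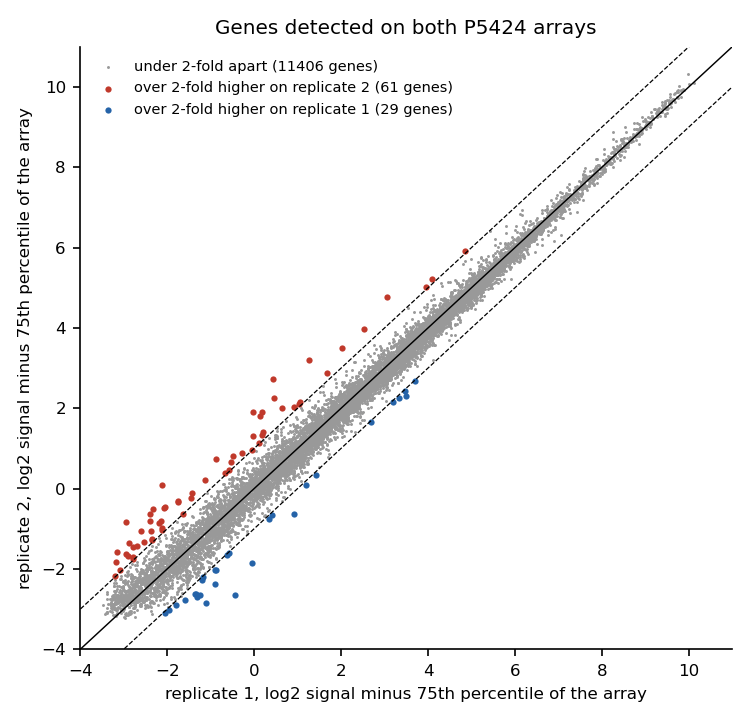
Log2 signal minus the array's 75th percentile of the 11496 genes detected on both arrays, replicate 1 on the x axis and replicate 2 on the y axis, 1 point per gene. The solid line marks equal values and the dashed lines a 2-fold difference; 61 genes lie above the upper line and 29 below the lower line.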

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

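The tests of background signal for the Rag2 and Trp53 probes and both tests of the B-cell genes were chosen after those results were seen, as were the counts of non-coding and receptor segment probes.

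Signal appeared on probes for transcripts outside the named genes. Of 16246 probes for long intergenic non-coding RNA, 3813 (23.5%) were well above background on both arrays, against 50.3% of the probes with a named gene. They cover 1834 of 4621 such loci, and at 582 loci every probe was detected. The median absolute difference between the arrays was 0.24 for the detected ones. In addition, 22 probes for T-cell receptor segments were well above background on both arrays, among them 15 of 32 alpha variable and 2 of 23 beta variable probes. The gene lists held 4 receptor segments, all of the gamma locus, which matched no gene on the array, so no receptor segment entered the list counts.

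Rag2 and Trp53 gave signal in a line labelled as lacking both. The lowest signal of the brighter Rag2 probe and the Trp53 probe was 9.89 times the highest negative control spot of the same array. For the dimmer Rag2 probe this ratio was 5.96 on replicate 1 and 0.879 on replicate 2, where 1 negative control spot reached 101 intensity units. Background stays open there. The probes were judged apart only after these ratios were seen, so the ratio of 9.89 describes signals away from the control spots and is no test. Control spots also cannot show whether other transcripts bind to a given probe, so unspecific signal is not excluded for any of these probes. Whether the probes lie outside the deleted part of each gene cannot be told apart from a partial loss, since the labels give the deleted part for 0 of the 3 probes. A transcript still made from a disrupted gene and a genotype other than the labelled one are therefore among the explanations left open, and these arrays can test neither.

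B-cell genes above background were also followed up. The lowest signals of Blnk and Pou2af1, the latter named after its values were seen, were 5.69 and 3.87 times the highest negative control spot of the same array. These genes were set apart by that same ratio, so it describes signals away from the detection limit and is no test of that limit. The other 6 detected genes lay at 2.51 to 17.6 times the highest spot on replicate 1. On replicate 2 they lay at 0.422 to 2.10 times it, a bound that rests on 1 outlying spot. A signal close to the detection limit therefore stays open for these 6. A limit planned as stricter decided nothing because it removed only 12 of the 11496 detected genes. B cells in the culture stay open too, since 8 of 18 genes of the whole list were detected, inside the range of random lists (5 to 13), and a first choice of 5 genes was dropped because it was made after their values were seen. The design gives no group to test a biological explanation, so none was tested.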

How the results depend on the processing

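Each result was recomputed under the alternatives that apply to it. The count of detected genes ranged from 9914 (every probe of a gene required) to 15005 (positive and significant signal), within 1.5 times of the reported count. With 1 array left out it was 11689 to 11876. The limit of 4 times the 95th percentile of the negative controls, meant to be stricter, gave 11625 genes. With a positive and significant signal as the criterion, detected members were 10 for progenitor, 14 for B-cell, 14 for myeloid, 6 for erythroid, 12 for stroma, 10 for other tissues and 14 for leukaemia genes, and 2 lists instead of 4 lay below the random range. Detection on 1 array sufficing gave 5 progenitor genes, and every probe required gave 1 progenitor, 3 myeloid and 3 stromal genes. Fisher's exact test kept its side of the threshold in 62 of 63 recomputations; the gamma-delta difference was 14.3 percentage points with a positive and significant signal (adjusted p = 0.233). The median absolute difference between arrays lay between 0.15 (normexp) and 0.30 (all probes). Genes over 2-fold apart numbered 34 with normexp and 635 with a positive and significant signal, and 557 genes passed 1.5-fold. No spot was saturated, so keeping saturated probes moved nothing. Median scaling added 3.99 to every level and the percentile over detected probes -3.51. Rag2 then stood at 6.76 and -0.75 and Trp53 at 5.46 and -2.04. Rag2 was 2.67 with normexp and 0.48 as the mean of its probes. Normexp moved the values of the other 153 named genes by a median of 0.39 (-0.51 to 3.30) and the authors' table by 0.08 (-0.12 to 2.67). These 153 include the named genes that were not well above background, so the ranges are not those of the detected genes alone. No paired analysis was possible because the arrays form 1 group.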

Other observations

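The test of spot noise was chosen after its result was seen, and the tests of differences by gene list and the account of the receptor segments were chosen after the files had been examined.

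Probes for T-cell receptor segments, counted by the descriptions in the files, covered the beta constant regions and few beta variable segments. Both beta constant region probes were well above background, constant region 1 at 8.98 (mean, n = 2) with signals of 163164 and 150814 intensity units, and constant region 2 at 8.73 ± 0.01. Of 23 probes for beta variable segments, 2 were detected on both arrays, variable 31 at -0.82 ± 0.18 and variable 13-1 at -2.68 ± 0.45, 1 was found on 1 array and 20 on neither. At the alpha locus, the constant region had a value of -1.05 ± 0.03, and 15 of 32 probes for variable segments were detected. Of all probes on the array, 40.1% were detected. On replicate 2 the signals of these alpha variable probes ranged from 33.6 (variable 7D-5) to 343 units (variable 15D-1-DV6D-1). Most lay below the highest negative control spot of that array (101 units), as did beta variable 13-1 (58.1) and delta variable 5 (51.6). Variable 6D-5 and 7D-5 each had another probe that was found on neither array. None of the 5 gamma variable probes was detected on both arrays, 1 was found on 1 array, and the gamma constant probe was not well above background. Of 3 delta variable probes, variable 5 was detected at -2.69 ± 0.22. Near-identical variable segments can share signal, so single segments are uncertain.

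Some genes outside the naming rule stood out after their values were seen. The granulocyte colony-stimulating factor receptor gene Csf3r, on the myeloid list, had a value of 7.69 ± 0.19 (chromosome 4, 125721478 to 125721537 of mm9). Cd74, the class II invariant chain, was 1.27 on replicate 1 and 3.20 on replicate 2. Cd5, a surface marker on which developing T cells carry their receptor signal strength, had values of 0.33 and 0.32.

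Whole lists differed slightly between the arrays. Of 22 lists with at least 5 detected genes, 5 had a median difference (replicate 2 minus replicate 1) outside the central 95% of random lists matched on mean signal, where chance gives 1.1, and the lists share genes. The T-lineage transcription factor (-0.16), DN3 (-0.20) and cytokine receptor (-0.23) lists were lower on replicate 2, and the interferon (0.18) and metabolism (0.13) lists were higher. The cell cycle list had a median difference of -0.04, inside its range of -0.11 to 0.04, with 10 of 22 genes higher on replicate 2. The cell cycle list was singled out before its difference was seen. After the median difference of probes with the same GC count was subtracted, 4 lists lay outside, 3 of them the same. The T-lineage transcription factor list (-0.12) and the DN3 list (-0.10) then lay inside their ranges, the former only just, and the T-lineage surface and signalling list (-0.12) newly lay below its range of -0.11 to 0.07. Normexp gave 7 lists and the values deposited by the authors gave 6, in each case with all 5.

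The 257 probes over 2-fold apart between the arrays were set against 3 technical explanations. For position on the array, 93.0% of the probes stayed over 2-fold apart after the medians of an 8 by 8 grid were subtracted (95% exact interval 89.2% to 95.8%). The block medians ranged only from -0.06 to 0.10, so little broad trend was left in the processed signals. The software had already subtracted a fitted spatial background and removed a trend over the array. Small block medians were thus partly fixed in advance, and the test covers only a trend left after these steps. A defect smaller than a block would not move its median, so the test cannot address it. Probe GC content may account for part of the pattern: subtracting the median of probes with the same GC count, which ranged from -0.36 to 0.31, left 79.8% over 2-fold apart (74.3% to 84.5%), just under the 80% set as the bound before this result was seen. Noise of single spots stays open under the plainest pairing, with other detected probes of the same named gene moving the same way in 61.3% of 142 cases (52.7% to 69.3%). This answer depends on how probes are paired: of 16 ways tried after the result was seen (the first one coded argued against noise), 11 argue against noise, 5 leave it open and none favours it. The share was 59.3% to 80% for named genes and 74.1% to 81.9% with unnamed loci counted as well, and no biological explanation was tested. The 16 ways share many probes and count direction only. Under the plainest pairing the median difference of the other probes in that direction was 0.15, and 0.41 with unnamed loci. Both lie below the log2 difference of 1 that marks a 2-fold change, so the tally of ways does not exclude noise.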
